A study of Mus musculus with 12 samples.

How the data were processed

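Livers of male and female CD-1 mice were the source of total RNA and of RNA from nuclei, which per the labels' protocols were isolated by homogenisation and ultracentrifugation through sucrose. Per the labels, RNA was extracted with Trizol, ribosomal RNA was depleted only in part, and the library kit kept strand. The labels assign 12 libraries to 4 groups, female total, male total, female nuclear and male nuclear RNA, with 3 pools of several mice each. All grouping was taken from these labels. The labels do not say that pools with a common number in total and nuclear RNA held the same mice. Lanes 3 and 4 are named in the labels, with all male total pools in lane 3 and all nuclear pools in lane 4.

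The submitters' processing notes name TopHat2, featureCounts and edgeR and the mouse genome build mm9, and their versions and settings are not given in the sources used here. Per the file headers and their legend, edgeR gave the lncRNA comparison, while for the RefSeq table the role of edgeR is not given. Per the file headers, the lncRNA table holds the authors' mean RPKM per group, the log2 fold change of males over females, a p-value and a false discovery rate for total and for nuclear RNA. Per the file headers, the RefSeq table holds the authors' mean FPKM per group, the male over female ratio, a signed fold change and an adjusted p-value. The deposited log2 values and ratios differ from the quotient of the deposited means by a factor per comparison, as values scaled between libraries would. Among rows over 1 in both sexes the SD of its log2 was 0.047 in total and 0.0089 in nuclear RNA for RefSeq genes. For lncRNAs it was 0.17 and 0.011, so the factor was less constant in total RNA. Single genes lay farther off, as Mup20 in total RNA with log2 6.07 deposited and 5.43 unscaled. Whether counting used the strand is not given in the sources used here, so genes that overlap on opposite strands are uncertain. The comparison header of the RefSeq table names the gene body. For 300 genes over 50 kb with the lowest female nuclear FPKM, however, 173 gave a whole implied length (within 0.01 bp) for 1 read in 1 library, against 17.6 by chance, and the median implied length was 2.88% of the gene span. All coordinates are those of the deposited tables on mm9, with starts counted from 1. A reference annotation of a later mouse build was used only for names, strand and approximate exonic length.

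The values were read in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. In 3 lncRNA rows the values were stored in another order and were put back, and 27 gene symbols stored as dates were restored. The deposited false discovery rates of lncRNAs were adjusted over 37893 features, judged from 1197 values of which 88.4% gave a whole rank within 0.01. No per-sample column was left unused (0), because both tables hold means and comparisons only.

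The planned tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Matched random lists and neighbouring pairs were chosen once the tables were found to hold means. A count model was planned, with limma on log2 values if no counts were held, both with the sex by fraction interaction, gene set tests (camera and fry) and the lncRNA share of counts. None of these could be run on means, so the calls rest on the adjusted p-values of the authors' deposited table at a threshold of 0.05, and the difference between the fractions has no test. For the same reason the counts adjusted over the list alone could not be computed, and whether replicates overlap could not be checked for named genes. Nuclear RNA was set against total RNA as log2((nuclear + 1)/(total + 1)) of the authors' mean values, less the median of the table, for entries with at least 1 FPKM or RPKM in a group. The pseudocount understates differences of low genes.

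Gene groups came from 43 fixed lists. The median of the members at 1 FPKM or more was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, where at least 3 members were measured. Such ranges describe these groups of libraries and are not tests over replicates. Overlaps of calls were compared with the product of both list sizes over the number of genes and with Fisher's exact test, one-sided, over genes, which are not independent replicates. Pairs of a called lncRNA and a called RefSeq gene within 100 kb were compared with 10000 permutations of direction among the lncRNAs. Shares carry 95% Wilson intervals, which cover counting error only. On simulated data, 3 of 100 lists of 20 genes among 9000 fell outside the central range without a shift and 47 of 100 with a shift of 0.5 SD. Of simulated sets of 80 pairs, 2 of 100 passed with no shared direction and 100 of 100 with 85% of pairs sharing one. The simulated genes and pairs were independent of each other, so these rates do not carry over to gene families or to pairs within a cluster.

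Genes named in the text followed a fixed rule. For each comparison these were the 10 with the largest difference in each direction among called genes with at least 5 FPKM in the higher group, and for lncRNAs the 5 in each direction with at least 1 RPKM. From each list the 2 called members with the largest difference per direction and the 2 most abundant members could be named, and any list member as an example. Nuclear against total RNA had no calls, so size in both sexes stood in their place. Genes called in opposite directions and the extra genes of the closing section were chosen after their values were seen. Some genes that the rule allows are not reported here.

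Library sizes are not listed in the tables and were recovered from the lowest values, which are whole multiples of what 1 read is worth in 1 library. With a relative tolerance of 1e-05, 92.1 to 100.0% of low values came out whole. The sizes were 6.43 to 13.8 M reads per library for the lncRNA table and 11.3 to 24.4 M for the RefSeq table, and they could not be assigned to pool numbers.

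The alternatives were a fold threshold, a minimum level in a group or in both fractions, another pseudocount, direction from the unscaled quotient of means, removal of families with near-identical copies, and another adjustment of the lncRNA p-values. Of the named genes, those with near-identical copies are uncertain because how shared reads were treated is not given in the sources used here. The legends of both tables were read for definitions only.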

Results

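Total RNA and nuclear RNA from the livers of untreated adult CD-1 mice, an outbred stock, were depleted of ribosomal RNA and sequenced in both sexes to find long noncoding RNAs (lncRNAs) and RefSeq genes that differ between male and female liver. The 12 libraries formed 4 groups of 3 pools (female total, male total, female nuclear and male nuclear RNA), and each pool held RNA of 12 to 17 mice aged 7 to 11 weeks. The measurements were the authors' mean FPKM of 24197 RefSeq genes and mean RPKM of 15558 lncRNAs per group (fragments or reads scaled to length and library size), with the authors' own comparison of males with females in each RNA fraction. Values per pool were not used here, so no SD is given and the error of each sex difference is carried by its adjusted p in the authors' deposited table. A gene or lncRNA was called when that adjusted p was under 0.05, and every log2 value between the sexes is male over female, so that a negative value means higher in females.

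Library sizes recovered from the lowest FPKM values of the RefSeq table were 17.9, 21.1 and 23.9 M reads (M, mega) in female total RNA and 11.3, 20.8 and 24.4 M in male total RNA. They were 21.4, 22.2 and 22.7 M in female nuclear RNA and 20.2, 22.2 and 22.6 M in male nuclear RNA. In the lncRNA table the recovered sizes ranged from 6.43 M reads for the smallest male total library to 13.8 M for the largest male total library. At these depths 3 counts per kb over the 3 pools of a group corresponded to 0.0452 to 0.0532 FPKM and to 0.0832 to 0.0939 RPKM, floors that cover counting error only and are lower for longer transcripts. All male total pools ran in lane 3 and all nuclear pools in lane 4, while 1 female total pool ran in lane 3 and the other 2 in lane 4. The comparison of the sexes in nuclear RNA therefore lay within lane 4. In total RNA sex and lane overlapped, as did RNA fraction and lane, and for these comparisons no value within a lane could be given.

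In total liver RNA, males had higher levels of most major urinary proteins, which carry pheromones, and of Cyp4a12a, a fatty acid hydroxylase, Elovl3, a fatty acid elongase, and Gstp1, a glutathione transferase. Females had higher levels of sulfotransferases of the Sult2a and Sult3a groups, of several cytochrome P450 enzymes of the Cyp2b, Cyp2a, Cyp2c and Cyp3a groups and of the plasma glycoprotein A1bg. Xist, the RNA that coats the inactive X chromosome, was abundant in females and close to 0 in males, and Y-linked genes had the opposite pattern. Genes of cholesterol and fatty acid synthesis, of the urea cycle and of the periportal zone of the liver lobule were more often called higher in females than in males, as were markers of macrophages and antigen presentation.

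The authors' deposited table called 731 RefSeq genes in total RNA, 344 higher in males and 387 higher in females, among 16404 genes above 0 in a group. Over 2-fold differences made up 136 of the male-higher and 160 of the female-higher calls in the authors' deposited table. The deposited log2 values exceeded the log2 quotient of the deposited means by a median of 0.48 in total RNA and 0.12 in nuclear RNA, so the median gene of at least 1 FPKM lay at -0.44 and -0.11 on the unscaled quotient. On that quotient 51 of the 725 called genes without a group at 0 in the total RNA comparison of the authors' deposited table had the other sign, which gave 291 male-higher and 434 female-higher genes.

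Mup20 (mm9 chromosome 4, 61711269 to 61715151) had the authors' mean of 5.40 FPKM in females and 233 in males, and Mup7 (chromosome 4, 60079341 to 60083347) 3.02 FPKM in females and 113 in males. In the authors' deposited table these corresponded to log2 6.07, adjusted p = 9.8e-106 for Mup20 and log2 5.79, adjusted p = 1.3e-23 for Mup7. Of 18 measured major urinary proteins, 15 were called higher in males, none in females and 3 in neither direction in the authors' deposited table. Their median in that comparison of the authors' deposited table was 3.83 over the 13 members at 1 FPKM or more, against -0.18 to 0.16 for the central 95% of expression-matched random lists. The most abundant members, Mup10 (332 FPKM in females and 856 in males) and Mup3 (209 FPKM in females and 526 in males), differed less, by log2 1.79 and 1.73 in the authors' deposited table. Mup genes are near-identical copies, so how reads were divided among them is uncertain.

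Mup21, Mup16, Mup14, Mup12 and Mup1 followed at log2 4.61, 4.47, 4.42, 3.83 and 3.69 in the authors' deposited table. Outside this family the leading male-higher genes with at least 5 FPKM in the higher group were Cyp4a12a and Elovl3. Cyp4a12a (chromosome 4, 114971651 to 115005420) had the authors' mean of 0.953 FPKM in females and 30.9 in males. Elovl3 (chromosome 19, 46206389 to 46210184) had 0.342 FPKM in females and 11.2 in males. Their values in the authors' deposited table were log2 5.49, adjusted p = 9.3e-81 and log2 5.47, adjusted p = 1.7e-103. The complement gene C4a, which has a close copy in C4b, stood at 0.690 FPKM in females and 5.33 in males (log2 3.46, adjusted p = 2.5e-115 in the authors' deposited table). Of 29 genes listed beforehand from the literature as male-biased in mouse liver, 27 were called higher in males and 2 were not called in the authors' deposited table. Among them were Cyp7b1, an oxysterol hydroxylase (log2 2.93, adjusted p = 9.5e-93), Hsd3b5, a steroid dehydrogenase (log2 2.63, adjusted p = 2.7e-33), and Gstp1 (log2 3.38, adjusted p = 2.5e-108) in the authors' deposited table.

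Of 44 measured genes listed beforehand as female-biased, 39 were called higher in females, 3 in males and 2 in neither direction in the authors' deposited table. The 3 called higher in males were Lpl, Ttc39c and Cib3, at log2 1.19, 2.49 and 3.78 in the authors' deposited table. A1bg (chromosome 15, 60749144 to 60752825) had the authors' mean of 251 FPKM in females and 1.19 in males, and Sult3a1 (chromosome 10, 33577528 to 33599281) 71.0 FPKM in females and 0.195 in males. The authors' deposited table gave log2 -7.28, adjusted p = 3.2e-54 for A1bg and log2 -8.17, adjusted p = 3.9e-181 for Sult3a1. Cyp3a41b, Cyp3a16, Gm4794, Cyp2b13, Sult2a1, Sult2a2 and Cyp3a41a had log2 -9.66, -8.32, -9.46, -7.82, -7.23, -7.16 and -7.15 in the authors' deposited table. The male means of Cyp3a41b (0.0143 FPKM), Cyp3a16 (0.0343 FPKM), Gm4794 (0.0155 FPKM) and Cux2 and the female mean of Cib3 (0.0245 FPKM) lay under the floor for a 1 kb transcript, which leaves the size of these differences imprecise. Cux2, a repressor known from female liver, stood at 1.32 FPKM in females and 0.0420 in males, and the prolactin receptor Prlr at 9.07 FPKM in females and 2.17 in males, with log2 -4.29 and -1.61 in the authors' deposited table.

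Drug-metabolising families split between the sexes. Of 48 measured cytochrome P450 genes of families 2 and 3, 18 were called higher in females and 9 in males, and 21 were not called in the authors' deposited table. Female-higher members included Cyp2b9 (58.1 FPKM in females and 0.781 in males) and Cyp2c39 (73.4 FPKM in females and 7.31 in males), and male-higher members Cyp2d9 (8.39 FPKM in females and 65.5 in males) and Cyp2c67 (8.90 FPKM in females and 33.3 in males). Their log2 values in the authors' deposited table were -5.77, -2.87, 3.46 and 2.38. Cyp2c29 and Cyp3a25 were male higher in the authors' deposited table (log2 0.46 and 0.42) and took the other sign on the unscaled quotient of means. In family 4, 4 of 17 measured genes were called higher in males, 3 in females and 10 in neither in the authors' deposited table. Besides Cyp4a12a, the lipid hydroxylase gene Cyp4a10 was lower in males (17.8 FPKM in females and 2.58 in males, log2 -2.29, adjusted p = 5.8e-28 in the authors' deposited table). Many of these P450 genes have near-identical neighbours, and their separate values are uncertain for that reason.

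Sulfotransferases were called higher in females in 8 of 16 measured cases, never higher in males, and 8 were not called in the authors' deposited table. Sult1a1 (32.7 FPKM in females and 8.63 in males) had log2 -1.44, adjusted p = 2.0e-32 in the authors' deposited table, and Sult2a3 was listed at 0 FPKM in males and 1.70 in females. UDP-glucuronosyltransferases, which conjugate bilirubin, steroids and drugs, were called higher in males in 5 of 18 and in females in 3 of 18 cases in the authors' deposited table, with 10 not called. Ugt2b1 was male higher and Ugt1a1 female higher, at log2 1.24 and -1.07 in the authors' deposited table. Glutathione transferases split 4 and 4 with 14 not called in the authors' deposited table, from Gstp1 in males to Gstt3 in females (log2 -2.07). Carboxylesterases were called higher in males in 5, in females in 2 and in neither in 9 of 16 cases in the authors' deposited table, with Ces3a at log2 1.12 and Ces1c at -0.57. Organic anion and cation transporters split 4 and 4 with 20 not called in the authors' deposited table, including Slco1a1 (log2 1.29) and Slc22a26 (log2 -5.74). Protease inhibitors of the Serpina1 and Serpina3 groups, again near-identical copies, were called higher in males in 5 of 15 cases and never in females in the authors' deposited table, with 10 not called.

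The called members of the cholesterol and fatty acid synthesis lists were higher in females in total RNA, while the elongase Elovl3, on neither list, was higher in males. Of 22 cholesterol synthesis genes 3 were called, all female higher, in the authors' deposited table: Sqle, Srebf2 and Sc5d, at log2 -0.55, -0.50 and -0.33. Of 21 fatty acid synthesis genes 5 were called, all female higher, in the authors' deposited table, among them the patatin-like phospholipase gene Pnpla3 (1.07 FPKM in females and 0.141 in males) and the ATP citrate lyase gene Acly (15.7 FPKM in females and 8.39 in males). The list medians of the authors' deposited table, -0.19 for cholesterol and -0.28 for fatty acid synthesis, lay under the matched ranges of -0.09 to 0.13 and -0.15 to 0.12. Such a placement among random lists does not depend on a common scaling factor. Of 26 fatty acid oxidation and PPARA target genes, 2 were called in each direction in the authors' deposited table, and the male-higher Creb3l3 and Hsd17b4 took the other sign on the unscaled quotient. Bile acid genes were called higher in males in 3 and in females in 1 of 18 cases in the authors' deposited table, led by the sterol carrier Scp2 (72.9 FPKM in females and 167 in males), while Amacr took the other sign on the unscaled quotient. Among 28 abundant plasma proteins 4 were male higher, 3 female higher and 21 not called in the authors' deposited table; albumin (Alb, 5481 FPKM in females and 2711 in males) was female higher at log2 -0.61, and Apob, male higher, took the other sign on the unscaled quotient.

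Nitrogen and zonation genes showed female-higher calls as well. Of 18 gluconeogenesis and urea cycle genes 6 were female higher, 1 male higher and 11 not called in the authors' deposited table, including the transaminase Got1 (20 FPKM in females and 5.03 in males, log2 -1.51) and Ass1, of the urea cycle (274 FPKM in females and 133 in males, log2 -0.56). The gluconeogenesis and urea cycle median of -0.19 in the authors' deposited table lay under its matched range of -0.14 to 0.15. Periportal markers were female higher in 7 and male higher in 2 of 17 cases in the authors' deposited table, and their median of -0.34 lay under the matched range of -0.12 to 0.15. Pericentral markers were female higher in 4 of 18 cases and never male higher in the authors' deposited table, with a median of -0.12 inside the matched range of -0.18 to 0.17. In growth hormone signalling, 5 of 19 genes were called, all female higher, in the authors' deposited table, among them Prlr, Igfbp1 (log2 -1.22) and Socs2 (log2 -0.73). The growth hormone list median of -0.36 in the authors' deposited table lay under its matched range of -0.16 to 0.13. Of 31 liver transcription factors 7 were female higher and 2 male higher in the authors' deposited table. They included Trim24 (log2 -1.79), the oestrogen receptor gene Esr1 (log2 -1.03) and, male higher, the repressor Bcl6 (log2 1.41) in the authors' deposited table. The clock list held 3 male-higher genes of 20, Dbp, Usp2 and Tsku, at log2 1.03, 1.32 and 1.42 in the authors' deposited table.

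A few markers of other liver cells were called in total RNA, most of them higher in females. Of 16 Kupffer cell and macrophage markers 3 were called, all female higher, in the authors' deposited table: Marco, Csf1r and Clec4f, at log2 -2.75, -0.52 and -0.47. Their list median in the authors' deposited table was -0.51, under the matched range of -0.20 to 0.11. In the same direction lay 2 of 10 MHC class II genes (Cd74, log2 -1.10, and H2-Ab1, log2 -1.53), 3 of 20 interferon-induced genes, 2 of 17 sinusoidal endothelial and 2 of 17 stellate cell markers in the authors' deposited table. The medians of the interferon (-0.77), endothelial (-0.18) and stellate (-0.28) lists in the authors' deposited table were under their matched ranges too, whose lower ends were -0.31, -0.13 and -0.21. Erythroid markers had 1 call of 10, Alas2 (2.02 FPKM in females and 6.76 in males, log2 2.22 in the authors' deposited table), and cholangiocyte markers 1 of 12, Spp1 (log2 0.82), both male higher. The erythroid list median of 0.40 in the authors' deposited table lay above its matched range of -0.23 to 0.21. However, Hbb-b1 and Hbb-bs, at nearly the same position, both had log2 0.40 there, and Hba-a1 and Hba-a2 both had 0.28. These members are not all separate measurements, so the placement may be overstated. No lymphocyte, neutrophil, pancreas or adipocyte marker was called among 17, 10, 11 and 2 measured in the authors' deposited table. The submitters' processing notes name edgeR among their tools, its role for the RefSeq table is not given in the sources used here, and unadjusted p values of RefSeq genes were not used. The counts of called genes were likewise 0 of 82 for ribosomal proteins, 0 of 75 for oxidative phosphorylation, 0 of 56 for histones, 0 of 25 for immediate early and heat shock genes and 0 of 15 for small nucleolar RNA host genes in the authors' deposited table. With none called, the immediate early and heat shock list still had a median of -0.20 in the authors' deposited table, under its matched range of -0.15 to 0.18. Of the housekeeping references 1 of 12 was called, Hprt at log2 0.66, and of the proliferation genes 1 of 20, Ccnd1 at log2 -1.35, in the authors' deposited table.

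The sex chromosomes gave the check on the labels. Xist (chromosome X, 100655712 to 100678572) had the authors' mean of 22 FPKM in females and 0.0215 in males, log2 -9.49 in the authors' deposited table. Ddx3y, Uty and Eif2s3y, on chromosome Y, were at 2.71, 1.13 and 3.12 FPKM in males and 0.0142, 0.00569 and 0.0326 FPKM in females, and Kdm5d was listed at 0 in females. All 4 measured Y-linked genes were called in the authors' deposited table. Of 11 X inactivation genes and X-linked partners, 4 were female higher in the authors' deposited table (Xist, Ftx, Kdm5c and Eif2s3x), and Usp9x was male higher there but took the other sign on the unscaled quotient. On the whole X chromosome 14 genes were female higher and 10 male higher in the authors' deposited table.

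**Figure D1:**
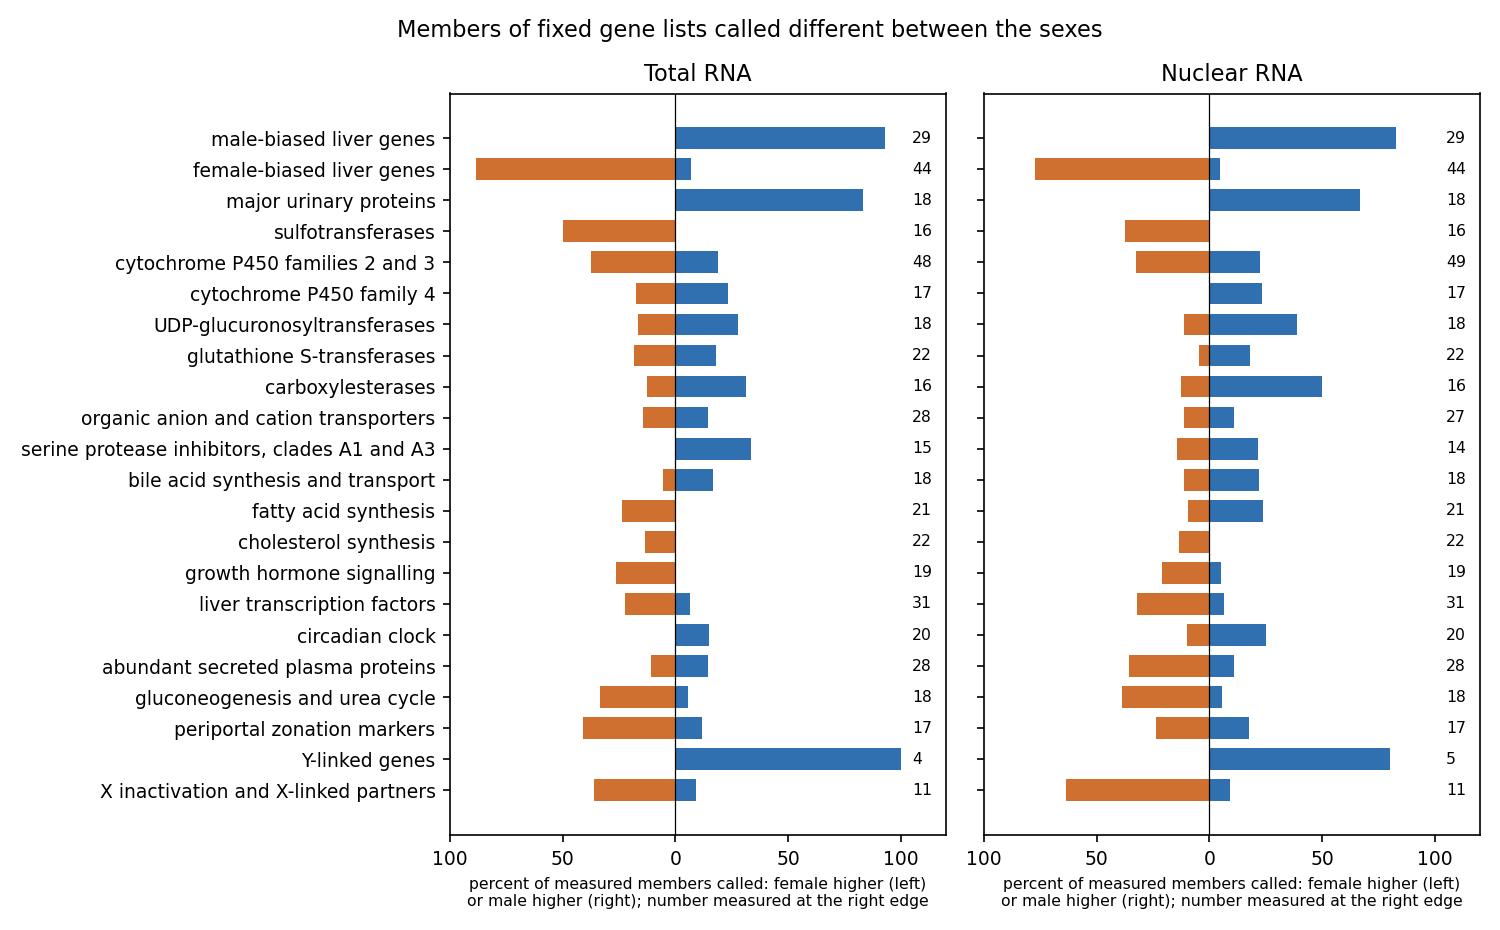
Percent of the measured members of 22 fixed gene lists called higher in females (orange, to the left) or in males (blue, to the right) in total and nuclear RNA, from the adjusted p in the authors' deposited table, with the number measured at the right edge. In total RNA 15 of 18 major urinary proteins lie on the male side and 8 of 16 sulfotransferases on the female side; among the male-higher total RNA calls, Cyp2c29, Cyp3a25, Amacr, Apob and Usp9x take the other sign on the unscaled quotient of means.

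In nuclear RNA, which holds transcripts before export, Cyp4a12a, most major urinary proteins, the complement genes C4a and C6, Cyp7b1, Hsd3b5 and Gstp1 were higher in males. Sult3a1, Cyp2b9, Cyp2b13, Cyp3a16, Cyp3a44, A1bg and Xist were higher in females. Carboxylesterases and glucuronosyltransferases were more often male higher, and plasma proteins, gluconeogenic genes and liver transcription factors more often female higher. No macrophage or antigen presentation marker was called in this fraction in the authors' deposited table, and most were low in it: 3 of 16 and 1 of 10 reached 1 FPKM, against 14 and 4 in total RNA.

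The authors' deposited table called 1013 genes in nuclear RNA, 492 higher in males and 521 in females, among 17467 above 0, and 147 and 134 of these differed over 2-fold. None of the 1006 calls without a group at 0 in the nuclear comparison of the authors' deposited table changed sign on the unscaled quotient. Cyp4a12a had the authors' mean of 0.0700 FPKM in females and 7.35 in males, C6 (chromosome 15, 4677210 to 4754045) 1.07 FPKM in females and 9.18 in males, Cyp7b1 (chromosome 3, 17971950 to 18143338) 0.715 FPKM in females and 6.88 in males, Hsd3b5 (chromosome 3, 98422559 to 98449457) 0.658 FPKM in females and 6.28 in males and Gstp1 (chromosome 19, 4035411 to 4037912) 1.41 FPKM in females and 14.1 in males. In the authors' deposited table these differences were log2 6.81, 3.21, 3.38, 3.37 and 3.41, the first with adjusted p = 2.9e-168. Mup7, Mup20, Mup21, Mup1 and C4a completed the 10 leading male-higher genes with at least 5 FPKM in males, at log2 6.30, 5.52, 5.34, 3.23 and 3.68 in the authors' deposited table. Sult3a1 stood at 40.7 FPKM in females and 0.0150 in males (log2 -10.94, adjusted p = 1.5e-310 in the authors' deposited table) and Cyp2b9 at 55.8 FPKM in females and 0.867 in males. Sult2a2 was listed at 0 FPKM in male nuclear RNA and at 6.66 in female nuclear RNA. Xist, A1bg, Cyp3a44, Cyp2b13, Cyp3a16 and Cyp2a4 had log2 -9.03, -7.96, -7.90, -7.57, -6.74 and -5.79 in the authors' deposited table. The male nuclear means of Sult3a1, Cyp3a44 and Cyp3a16 lay under the floor for a 1 kb transcript, so these sizes are imprecise.

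The literature lists gave 24 male-higher calls and 5 not called of 29 male-biased genes, and 34 female-higher, 2 male-higher and 8 not called of 44 female-biased genes, in nuclear RNA in the authors' deposited table. Major urinary proteins were male higher in 12 of 18, and sulfotransferases female higher in 6 of 16 cases in the authors' deposited table. P450 families 2 and 3 held 16 female-higher and 11 male-higher genes of 49, and family 4 held 4 male-higher genes of 17, in the authors' deposited table. Glucuronosyltransferases were male higher in 7 and female higher in 2 of 18 cases, and carboxylesterases male higher in 8 and female higher in 2 of 16 cases in the authors' deposited table. Examples were Ugt2b5 (5.15 FPKM in females and 12.7 in males, log2 1.42), Ces1e (3.16 FPKM in females and 7.90 in males, log2 1.44) and Ces1b (11.2 FPKM in females and 4.82 in males, log2 -1.10) in the authors' deposited table. The medians of both lists in the authors' deposited table, 0.52 and 0.89, lay above the matched ranges of -0.21 to 0.17 and -0.30 to 0.25. In total RNA their medians of 0.29 and 0.28 in the authors' deposited table also lay above the matched ranges, which ended at 0.14 and 0.20. Glutathione transferases had 4 male-higher and 1 female-higher call of 22, transporters 3 and 3 of 27, and Serpina1 and Serpina3 genes 3 male-higher and 2 female-higher calls of 14 in the authors' deposited table. Those 2 were Serpina3n (41.3 FPKM in females and 15.5 in males) and Serpina3m (15.7 FPKM in females and 7.08 in males), at log2 -1.29 and -1.03 in the authors' deposited table.

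Of 28 plasma protein genes, 10 were female higher and 3 male higher in nuclear RNA in the authors' deposited table, and their median of -0.20 lay just under the matched range of -0.18 to 0.16. Itih4 (112 FPKM in females and 51.4 in males, log2 -1.01) and the complement gene C3 (108 FPKM in females and 55.9 in males, log2 -0.83) led the female-higher members, and Apoa1 (35.4 FPKM in females and 48.4 in males, log2 0.58) the male-higher ones, in the authors' deposited table. Gluconeogenesis and urea cycle genes were female higher in 7 and male higher in 1 of 18 cases in the authors' deposited table, with Pck1, which commits carbon to glucose, at 63.2 FPKM in females and 35.8 in males (log2 -0.69). Liver transcription factors were female higher in 10 and male higher in 2 of 31 cases in the authors' deposited table. They included Hnf4a (12.8 FPKM in females and 8.70 in males, log2 -0.44), Prox1 (11.2 FPKM in females and 5.98 in males, log2 -0.79) and, male higher, Ppara (4.82 FPKM in females and 7.15 in males, log2 0.69) in the authors' deposited table. In growth hormone signalling 4 of 19 genes were female higher, and the receptor gene Ghr itself was male higher at 7.46 FPKM in females and 10.7 in males (log2 0.64), in the authors' deposited table. The clock list held 5 male-higher and 2 female-higher genes of 20 in the authors' deposited table, with the output gene Dbp at log2 1.82 and the activator Arntl at -0.51. Its median of 0.32 in the authors' deposited table lay above the matched range of -0.20 to 0.16. Time of day at collection was not among the label entries used here, and its part in the clock calls of either fraction was not tested.

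Fatty acid synthesis genes were male higher in 5 and female higher in 2 of 21 cases in nuclear RNA in the authors' deposited table, with Scd1, a fatty acid desaturase, at 4.02 FPKM in females and 7.49 in males (log2 1.01). The fatty acid oxidation list had 2 male-higher genes of 26, cholesterol synthesis 3 female-higher of 22, bile acid genes 4 male-higher and 2 female-higher of 18, and pericentral markers 4 female-higher and 1 male-higher of 18 in the authors' deposited table. Periportal markers were female higher in 4 and male higher in 3 of 17 cases in the authors' deposited table. Their median of -0.26 in the authors' deposited table lay just under the matched range of -0.25 to 0.19. No member was called among 16 macrophage, 10 MHC class II, 17 endothelial, 17 stellate, 11 cholangiocyte, 17 lymphocyte, 12 pancreas, 76 oxidative phosphorylation and 56 histone genes in the authors' deposited table. A single member was called in the lists of interferon-induced (Oas2, female higher), proliferation (Ccnd1, female higher), immediate early (Gadd45g, female higher), erythroid (Alas2, male higher), neutrophil (Cxcr2, male higher), adipocyte (Adrb3, male higher), ribosomal protein (Rpl14, male higher), small nucleolar RNA host (Snhg11, male higher) and housekeeping genes (Polr2a, female higher) in the authors' deposited table. The medians of the oxidative phosphorylation (0.15) and housekeeping lists (0.24) in the authors' deposited table nevertheless lay above their matched ranges of -0.09 to 0.09 and -0.23 to 0.20. The glutathione transferase median of 0.46 in the authors' deposited table lay above its range of -0.27 to 0.26 too. Whether the nuclei of both sexes were equally free of cytoplasmic RNA was not tested. Xist reached 94.0 FPKM in females and 0.162 in males, and 7 of 11 X inactivation genes and partners were female higher in the authors' deposited table, among them Jpx (log2 -0.83), Kdm5c (log2 -0.85) and Kdm6a (log2 -0.61). Tsix was also female higher at log2 -4.84 in the authors' deposited table, but it overlaps Xist on the other strand and whether counting used the strand is not given in the sources used here. Of 5 measured Y-linked genes 4 were called in the authors' deposited table, with Uty at 3.97 FPKM in males.

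Sex differences in the total and nuclear fractions were then compared gene by gene. Of the genes above 0 in both fractions, 193 were called male higher in both and 170 female higher in both in the authors' deposited table. Independent lists of these sizes among 15980 genes would share 10.6 and 12.6, and the one-sided Fisher exact p over genes were 3.5e-211 and 4.9e-155. The fractions shared no libraries. A called gene had the same sign in the other fraction in 637 of 731 cases (87.1%) from total RNA and 880 of 1012 (87.0%) from nuclear RNA in the authors' deposited table. A further 11 genes were called in opposite directions in the authors' deposited table. Of these, Saa1 and Saa2, serum amyloid genes of the acute-phase response, Lcn2, an iron-carrier binding protein, Hpx, a haem binding protein, Orm1, a plasma glycoprotein, and A2m, a protease inhibitor, were male higher in total and female higher in nuclear RNA. So were Nrbp2, 1810055G02Rik and Ldha, a lactate dehydrogenase gene whose total RNA difference (log2 0.34 in the authors' deposited table) took the other sign on the unscaled quotient. Acss2 and Clec2d went the other way. A2m stood at 0.00936 FPKM in females and 0.0938 in males in total RNA, near the floor, so the size of its difference is imprecise. Saa1 had the authors' mean of 62.4 FPKM in females and 158 in males in total and 73.4 FPKM in females and 51.3 in males in nuclear RNA, and Lcn2 10.5 FPKM in females and 15.9 in males in total and 14.1 FPKM in females and 3.48 in males in nuclear RNA. The adjusted p of Saa1 in the authors' deposited table were 1.4e-05 in total and 0.032 in nuclear RNA. The difference between the fractions was itself not tested, since no values per pool were used.

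**Figure D2:**
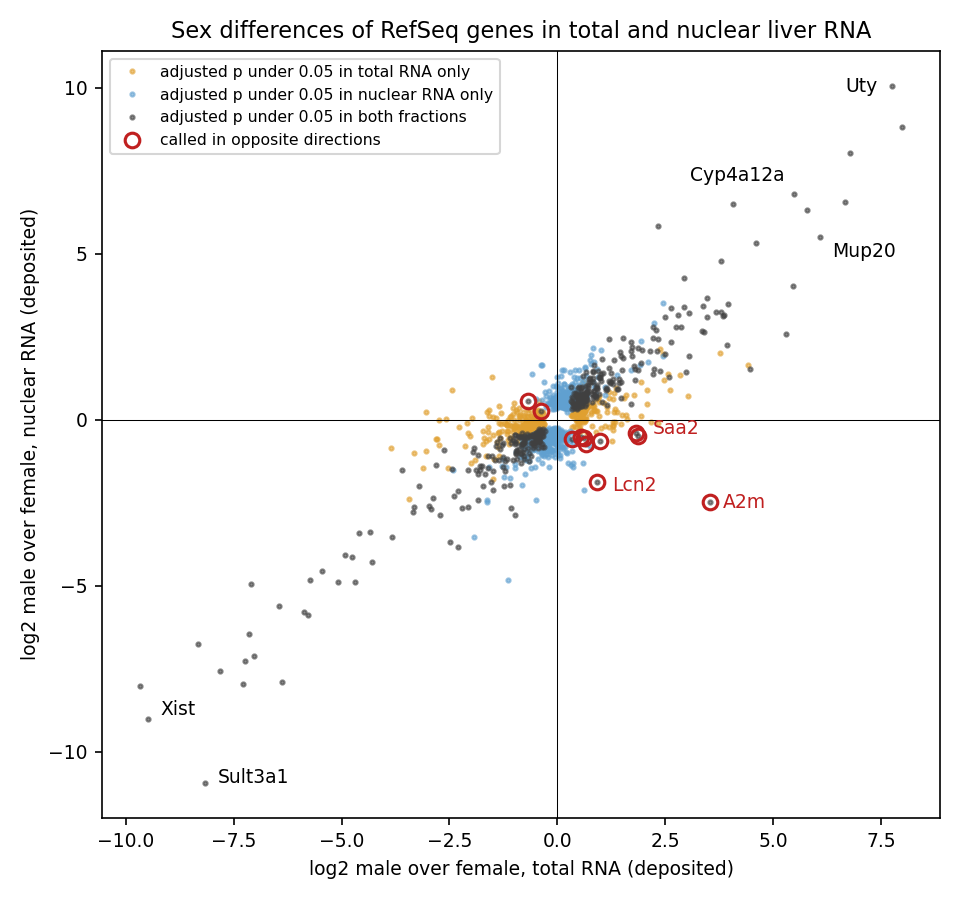
The log2 male over female difference in total RNA (horizontal) and nuclear RNA (vertical), from the authors' deposited table, of RefSeq genes called in either fraction and above 0 in all 4 groups, with a point per gene. The red circles are the 11 genes called in opposite directions, with A2m farthest out at log2 3.54 in total and -2.47 in nuclear RNA, at total RNA levels near the floor; Ldha, among them, takes the other sign in total RNA on the unscaled quotient.

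Among lncRNAs, the leading female-higher transcripts included Xist, spliced transcripts lying within the Cyp3a and Sult2a gene clusters and single-exon transcripts near A1bg. The male-higher transcripts included an antisense RNA across the Mup20 region and intergenic RNAs near Bcl6 and Klf9. More lncRNAs were called in nuclear than in total RNA. Of the sense transcripts inside genes that were called, most were female higher.

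In total RNA 145 lncRNAs were called, 70 male higher and 75 female higher, among 10708 above 0 in the authors' deposited table. In nuclear RNA 641 were called, 303 male higher and 338 female higher, among 13120 above 0 in the authors' deposited table. Counting only lncRNAs with at least 1 RPKM in the higher group left 12 male-higher and 21 female-higher in total RNA and 107 and 192 in nuclear RNA in the authors' deposited table. By class, nuclear RNA held 245 male-higher and 274 female-higher of 13343 intergenic lncRNAs, 53 and 38 of 1966 antisense lncRNAs, and 5 and 26 of 249 intragenic sense lncRNAs in the authors' deposited table. In total RNA the same classes held 56 and 53, 13 and 7, and 1 and 15 in the authors' deposited table. On chromosome X 8 lncRNAs were female higher and 3 male higher in nuclear RNA, and on chromosome Y 2 were male higher, in the authors' deposited table.

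The antisense lncRNA ncRNA_as_chr4_3297 (chromosome 4, 61534877 to 61748241, 2 exons) overlaps Mup20 on the other strand and had the authors' mean of 0.744 RPKM in females and 6.05 in males in total RNA (log2 3.72, adjusted p = 2.5e-04 in the authors' deposited table). Its reads cannot be told from those of the Mup genes unless the counting used strand. The intergenic ncRNA_inter_chr16_13170 (chromosome 16, 24076567 to 24098742, 5 exons), 87.9 kb from Bcl6, had 0.972 RPKM in females and 2.13 in males in total and 1.78 RPKM in females and 6.26 in males in nuclear RNA. Its log2 values in the authors' deposited table were 1.61 and 1.92, and those of Bcl6 1.41 and 0.92. The intergenic ncRNA_inter_chr5_4368 near Alb, ncRNA_intra_chr6_5591 inside Mug1 and ncRNA_as_chr15_12817 across Pkdrej completed the leading male-higher lncRNAs with at least 1 RPKM in total RNA, at log2 2.38, 1.80 and 1.58 in the authors' deposited table. In nuclear RNA the first (log2 -0.48) and second (log2 0.47) were not called and the third (log2 1.29) was called male higher in the authors' deposited table. The lncRNA record of Xist (chromosome X, 100655410 to 100678927, 10 exons) stood at 38.9 RPKM in females and 0.0370 in males in total and 168 RPKM in females and 0.293 in males in nuclear RNA. ncRNA_intra_chr5_4728 (chromosome 5, 146227188 to 146406523, 2 exons), a sense transcript, had 8.23 RPKM in females and 0.00668 in males in nuclear RNA (log2 -9.81, adjusted p = 7.7e-123 in the authors' deposited table). It contains Cyp3a41b (146319533 to 146345599) and overlaps Cyp3a41a, which is listed at 2 locations. Its neighbours ncRNA_intra_chr5_4741, ncRNA_intra_chr5_4726 and ncRNA_intra_chr5_4740 were listed at 0 RPKM in male total RNA and at 1.61, 2.14 and 2.77 RPKM in female total RNA. These sense transcripts overlap P450 genes that have near-identical copies, so their values are uncertain. The male means of ncRNA_intra_chr5_4728 in both fractions and of the Xist record in total RNA lay under the floor for a 1 kb transcript, so these sizes are imprecise.

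In nuclear RNA ncRNA_inter_chr19_14873 (chromosome 19, 23135639 to 23148147, 5 exons), 67.6 kb from Klf9, had the authors' mean of 0.118 RPKM in females and 2.98 in males (log2 4.76, adjusted p = 2.1e-118 in the authors' deposited table). ncRNA_inter_chr4_3468, which carries the RefSeq name Gm12718 (chromosome 4, 103055088 to 103169173, 4 exons), had 0.0573 RPKM in females and 2.04 in males (log2 5.22, adjusted p = 6.5e-69 in the authors' deposited table). The single-exon ncRNA_inter_chr6_5862 near Amn1, ncRNA_inter_chr4_3287 at Mup2 and ncRNA_inter_chr8_6982 near Enpp6 had log2 4.81, 4.49 and 3.88 in the authors' deposited table. The female nuclear means of ncRNA_inter_chr4_3468, ncRNA_inter_chr6_5862 (0.0395 RPKM) and ncRNA_inter_chr4_3287 (0.0531 RPKM) lay under the floor for a 1 kb transcript and that of ncRNA_inter_chr8_6982 (0.101 RPKM) just above it, which leaves the sizes imprecise. On the female side ncRNA_inter_chr15_12590 and ncRNA_inter_chr15_12591, 11.3 and 8.88 kb from A1bg, were listed at 0 RPKM in males and at 2.71 and 2.11 in females. The same held for ncRNA_intra_chr7_5920 at Sult2a1, at 5.64 RPKM in females.

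Of lncRNAs above 0 in both fractions, 51 were male higher in both and 64 female higher in both in the authors' deposited table, where independent lists among 10401 would share 1.99 and 2.39 (one-sided Fisher exact p = 6.9e-65 and 9.9e-87 over lncRNAs). Opposite calls in the authors' deposited table numbered 6, of which 5 lie close together on chromosome 2 near B3galt1. Of these, ncRNA_inter_chr2_1419 (67808739 to 67880891) spans the others on the other strand. The adjoining ncRNA_inter_chr2_1420, ncRNA_inter_chr2_1421 and ncRNA_inter_chr2_1422 had near-equal means (54.7, 55.9 and 57.3 RPKM in female nuclear RNA). The 5 may therefore not be separate transcripts. The share called in nuclear RNA climbed with level, from 4.44% (95% Wilson interval 3.85 to 5.11) at 0.2 to 0.5 RPKM to 21.3% (18.3 to 24.7) at 1 to 2 RPKM in the authors' deposited table. In total RNA the shares in these ranges were 3.93% (2.91 to 5.29) and 8.45% (4.90 to 14.2) in the authors' deposited table. At 2 to 5 RPKM the nuclear and total shares were 25.2% (21.2 to 29.7) and 21.4% (13.4 to 32.4), and at 5 to 10 RPKM 25.8% (18.8 to 34.3) and 23.5% (9.56 to 47.3, 17 lncRNAs), with overlapping intervals, in the authors' deposited table. At 10 RPKM or more they were 40.2% (30.6 to 50.7) and 7.69% (2.14 to 24.1, 26 lncRNAs) in the authors' deposited table.

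**Figure D3:**
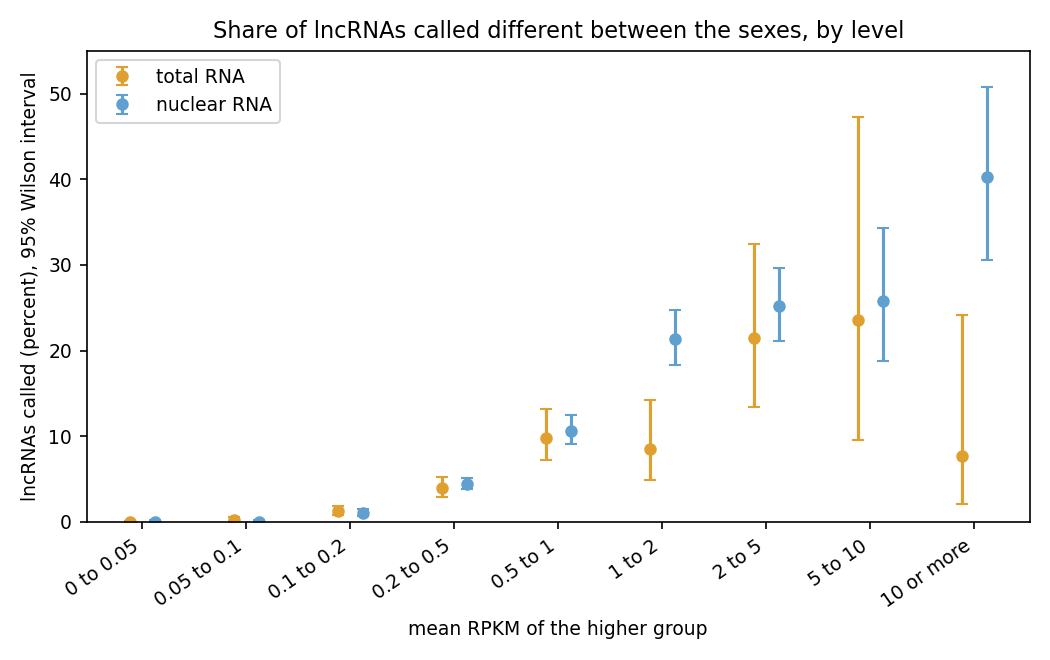
Percent of lncRNAs called different between the sexes in the authors' deposited table against the mean RPKM of the higher group, in total RNA (yellow) and nuclear RNA (blue), with 95% Wilson intervals as bars. At 1 to 2 RPKM the intervals are 4.90 to 14.2 in total and 18.3 to 24.7 in nuclear RNA, while from 0.2 to 1 RPKM and from 2 to 10 RPKM the intervals of the fractions overlap.

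Called lncRNAs and called genes close to each other were mostly higher in the same sex. In nuclear RNA, 398 of 434 pairs of a called lncRNA and a called RefSeq gene within 100 kb (91.7%) had a common direction in the authors' deposited table, with 259 lncRNAs and 213 genes in the pairs. In 10000 permutations of direction among the lncRNAs the 95th percentile was 56.0% and the highest 64.1% (permutation p = 0.0001, one-sided, the smallest these permutations can give). In total RNA 104 of 129 pairs (80.6%) had a common direction in the authors' deposited table, against a 95th percentile of 58.9% (permutation p = 0.0001, one-sided, again the smallest possible). Pairs in the same gene cluster, such as those at Cyp3a41a, are not independent, and the permutations treated them as if they were.

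Nuclear RNA was compared with total RNA on the authors' mean levels. The nucleus was rich in known nuclear lncRNAs such as Malat1 and Neat1, in small nucleolar RNA host transcripts, in single short RNAs such as Snora61 and the RNase MRP RNA Rmrp and in several transcription factor mRNAs. Total RNA was rich in mRNAs of secreted plasma proteins such as albumin, in ribosomal protein, oxidative phosphorylation and haemoglobin mRNAs and in the desaturase Scd1. Values are given per sex or, where stated, over the sexes, there is no test because values per pool were not used, and all values are log2((nuclear + 1)/(total + 1)) less the median gene of that sex.

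Among 7306 genes with at least 1 FPKM in a group, 622 (8.51%) were over 2-fold higher in nuclear and 1055 (14.4%) over 2-fold higher in total RNA, relative to the median gene. The median before this centring was -0.30 in females and -0.08 in males. RefSeq genes with only noncoding accessions (578) had a median of 1.18 in females and 0.99 in males, and 55% of them were over 2-fold nuclear on the mean of the sexes. Genes with a coding accession (6728) had a median of -0.07 in each sex. With a pseudocount of 0.1 the noncoding median exceeded the coding median by 2.15 in place of 1.13, and the counts over 2-fold became 1583 and 1613. The excess was 0.15 with no minimum level, 2.61 with a minimum of 5 FPKM and 1.05 with 1 FPKM required in both fractions, which left 334 genes over 2-fold nuclear, so these sizes depend on how low genes are treated. Noncoding genes passed a minimum in any group mostly through nuclear RNA, where 556 reached 1 FPKM against 259 in total RNA. This can favour the nuclear side, and its share in the excess was not tested.

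The nuclear-retained lncRNAs had a list median of 1.93 in females and 1.29 in males, and their mean over the sexes, 1.49, exceeded the matched range of -1.32 to 0.62. Malat1 was at 737 and 592 FPKM in female and male nuclear RNA against 201 and 118.02 in total RNA, and Neat1 at 104 and 67.7 against 29.2 and 9.74. The small nucleolar RNA host genes followed with 1.08 and 0.96 (matched range -0.46 to 0.63), and Rmrp had 2.68 and 3.08. The genes with the largest nuclear excess included the small nucleolar RNAs Snora61 at 3.63 and 3.84, Snora23 at 2.60 and 3.37 and Snora74a at 2.56 and 3.09 in females and males, as well as Mir292b, Mir3069, Snord15a, Snord15b and Snora5c. How far such short RNAs enter these libraries is not known from the files, and some sit inside introns of other transcripts. The pseudogene Serpina4-ps1 stood at 162 and 183 FPKM in nuclear against 25.3 and 35.7 in total RNA. Liver transcription factors had a list median of 0.38 over the sexes, above the matched range of -0.66 to 0.24, with Nr1i3, a xenobiotic receptor, at 1.55 and 1.71.

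On the other side, albumin (Alb) was at 5481 and 2711 FPKM in female and male total RNA and at 238 and 189 in nuclear RNA, a relative log2 of -4.21 and -3.76. Scd1 (-4.87 and -3.71), Gm2083 (-4.18 and -4.08), Apoe (-4.05 and -3.51), Apoa2 (-3.91 and -3.33) and Hsd11b1 (-3.86 and -3.30) stood with it, as did Mup10, Serpina1b and the haemoglobin genes Hbb-b1 and Hbb-bs. Plasma proteins as a list had medians of -2.15 and -2.39 in females and males, ribosomal proteins -2.31 and -2.20, oxidative phosphorylation genes -2.0 and -1.79 and erythroid markers -3.21 and -3.19. The medians over the sexes of these 4 lists (-2.19, -2.26, -1.91 and -3.20) all lay under their matched ranges, which began at -1.80, -1.28, -0.91 and -0.92. Hbb-b1 and Hbb-bs share nearly all of their span, so the erythroid placement rests on fewer separate measurements than members. Also over the sexes, glutathione transferases (-1.73), Serpina1 and Serpina3 genes (-2.49), major urinary proteins (-2.0), housekeeping references (-1.60), pericentral markers (-1.68), UDP-glucuronosyltransferases (-1.20), cholesterol synthesis genes (-0.97), histones (-0.68) and macrophage markers (-0.76) lay under theirs as well. Within this group the medians differed between the sexes for major urinary proteins (-1.28 in females and -2.72 in males), glutathione transferases (-1.98 and -1.42) and macrophage markers (-1.06 and -0.52). The added 1 narrows ratios of low levels, so these gaps cannot be read as sex differences in the nuclear share. Mup20 stood at 0.305 FPKM in female and 13.2 in male nuclear RNA, against 5.40 and 233 in total RNA. Of 16 macrophage markers 3 reached 1 FPKM in nuclear RNA. Which liver and blood cells the isolated nuclei came from was not tested. The erythroid and macrophage values therefore need not show location within a cell. Bile acid, gluconeogenesis, fatty acid oxidation and transporter genes had medians over the sexes within the matched ranges.

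**Figure D4:**
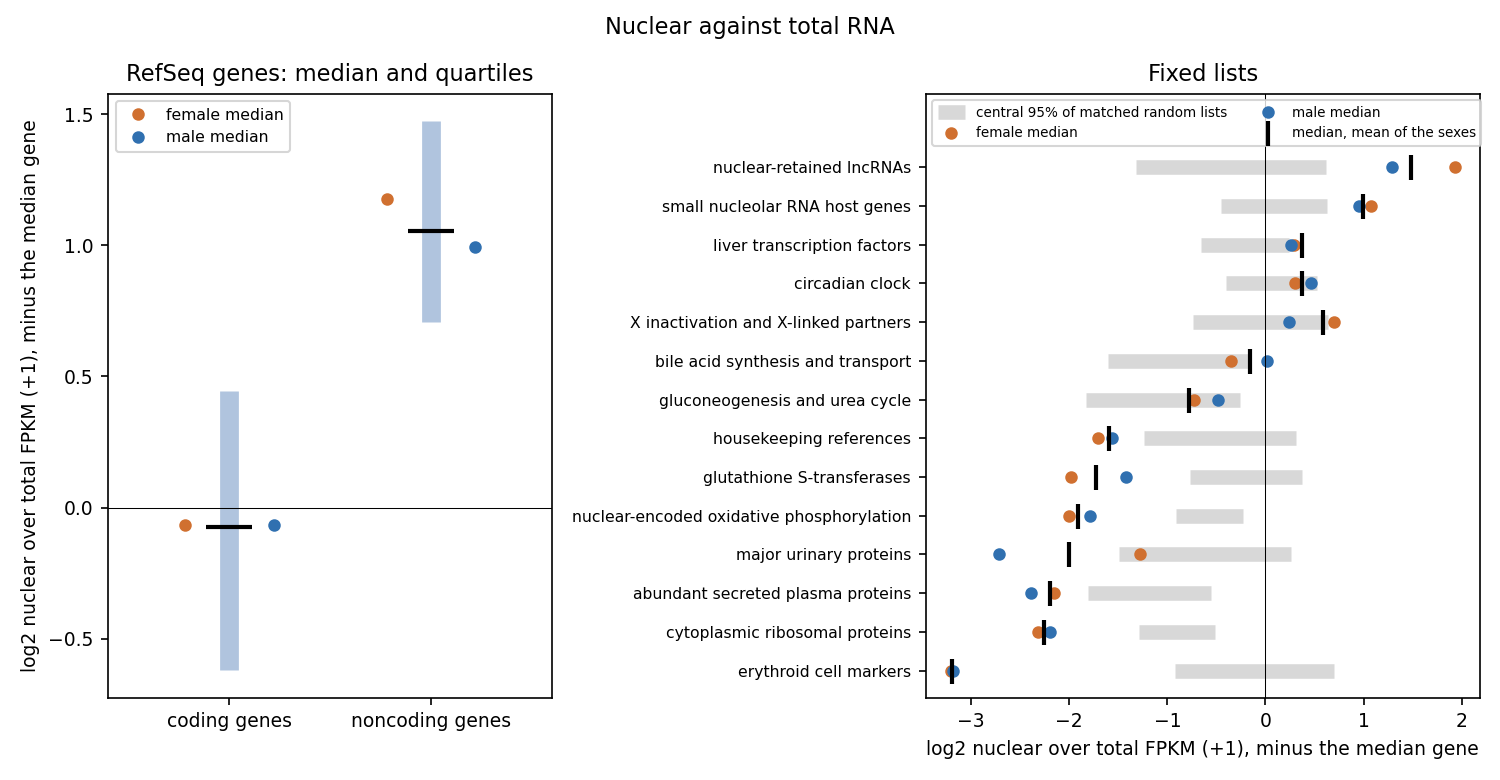
Left, log2 nuclear over total FPKM (with 1 added, less the median gene) of 6728 coding and 578 noncoding RefSeq genes, with the median as a line, quartiles as the bar and the sexes as points. Right, medians of 14 fixed lists on the same scale with the central 95% of matched random lists in grey; erythroid markers lie at -3.20 and nuclear-retained lncRNAs at 1.49.

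The 1237 lncRNAs with at least 1 RPKM in a group had an uncentred median of 0.96 in each sex. It was 1.92 with a pseudocount of 0.1, 0.15 with no minimum, 1.66 with a minimum of 5 RPKM and 1.47 with 1 RPKM required in both fractions, against 0.93 for the mean of the sexes in the main setting. Of these lncRNAs 1228 reached 1 RPKM in nuclear and 255 in total RNA. Relative to the median lncRNA, ncRNA_inter_chr12_10880 at Serpina4-ps1 (3.48 and 3.45 in females and males), ncRNA_inter_chr4_3685 at Snhg3 (3.27 and 3.57) and ncRNA_inter_chr18_14604 at Mir122 (2.98 and 2.62) were the most nuclear with ncRNA_as_chr12_10887 and ncRNA_as_chr6_5590. Each overlaps a RefSeq gene. On the total RNA side stood ncRNA_inter_chr14_12016, the RNase P RNA Rpph1 (-2.85 and -1.98), and ncRNA_inter_chr17_13909, the ribosomal precursor Rn45s. Rn45s remained at 51461 and 60908 RPKM in female and male total RNA and 19932 and 26285 RPKM in nuclear RNA, the measured residue of a depletion that the labels describe as partial.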

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

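The tests of an acute-phase state, with its repeat on the unscaled quotient, and of neutrophils were chosen after the opposite directions had been seen. The 17 genes and lncRNAs given here were called in both RNA fractions with opposite directions in the authors' deposited table. The difference between the fractions was not tested, since this needs values per pool, and other splits of the libraries could not be drawn for the same reason.

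As the log2 male over female value in total RNA minus that in nuclear RNA, both from the authors' deposited table, the genes higher in males in total RNA differed by 6.01 for A2m, 2.22 for Saa1, 2.37 for Saa2, 2.81 for Lcn2, 1.16 for Hpx, 1.40 for Orm1, 1.06 for Nrbp2, 1.63 for 1810055G02Rik and 0.92 for Ldha. On the unscaled quotient this difference has a median of -0.37 over all genes, against -0.0072 on the deposited scale, so the values depend on the scaling by about that much. A2m was near the floor in total RNA, and Ldha takes the other sign in total RNA on the unscaled quotient. Nrbp2 had nearly equal means in total RNA, 1.59 FPKM in females and 1.63 in males. The pair higher in females in total RNA differed by -0.64 for Clec2d and -1.26 for Acss2 in the authors' deposited table. Among lncRNAs the same difference in the authors' deposited table was 1.57 for ncRNA_as_chr1_978, which overlaps Prox1 on the other strand. It was 4.56 for ncRNA_inter_chr2_1419, 2.23 for ncRNA_inter_chr2_1420, 2.09 for ncRNA_inter_chr2_1421, 2.14 for ncRNA_inter_chr2_1422 and 1.94 for ncRNA_inter_chr2_1426 in the authors' deposited table. Deposited lncRNA values exceeded the unscaled quotient by a median of 0.52 in total and 0.11 in nuclear RNA, so these differences also depend on the scaling. The mean levels of ncRNA_inter_chr2_1419 in total RNA lay under the floor, so its difference is imprecise. B3galt1, the RefSeq gene nearest to these 5, was male higher in total RNA at log2 1.29 and not called in nuclear RNA at -0.30 in the authors' deposited table.

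Saa1, Saa2, Lcn2, Hpx and Orm1 belong to the acute-phase response of the liver, and the pattern was weighed on other genes of that response. A2m, near the floor in total RNA, was grouped with them here and adds little. Neutrophils in the libraries are argued against, because the highest of 10 neutrophil markers, S100a8, reached 0.571 FPKM, while the highest levels of Saa1, Saa2, Hpx and Orm1 were 121 FPKM or more. Of 32 other acute-phase genes, the 28 at 1 FPKM or more had a median of 0.580 for total minus nuclear log2 in the authors' deposited table, above the range of -0.14 to 0.14 of matched random lists, with 27 of 28 above 0; on the unscaled quotient the median was 0.19 with 21 of 28 above 0, also above its matched range of -0.50 to -0.22. The median was 0.64 over the 22 genes that are not on the plasma protein list, and in nuclear RNA 16 of the 28 were called female higher and 0 male higher (median log2 -0.50), against 3 in each direction in total RNA (median log2 0.07), in the authors' deposited table. These values are consistent with a different acute-phase state of the mice or pools behind the total and nuclear libraries, which remains a hypothesis: the other genes show the female-higher nuclear side and not a male-higher total RNA side, and the lane of the total RNA pools and the timing of transcription against mRNA level stay open.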

How the results depend on the processing

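Chosen after seeing the data were the unscaled quotient, removal of near-identical families, another adjustment, the deposited sex flag, and no minimum, a minimum of 5 or 1 in both fractions for nuclear against total RNA. All other settings were planned. With an absolute log2 over 1, the authors' deposited table held 136 male-higher and 160 female-higher RefSeq genes in total RNA and 147 and 134 in nuclear RNA. With a minimum mean of 1, the lncRNA calls in the authors' deposited table were 12 and 21 in total RNA and 107 and 192 in nuclear RNA. The deposited flag gave 38 and 44, and 124 and 139. With log2 over 1 in both fractions, 81 male-higher and 73 female-higher RefSeq genes were shared, and 1 RefSeq gene (A2m) and 2 lncRNAs (ncRNA_inter_chr2_1420 and ncRNA_inter_chr2_1422) lay in opposite directions in the authors' deposited table. For nuclear against total RNA, a pseudocount of 0.1 gave a noncoding minus coding median of 2.15, 1583 and 1613 genes over 2-fold and a lncRNA median of 1.92. No minimum gave 0.15, 380 genes over 2-fold nuclear and 0.15. A minimum of 5 gave 2.61, 265 genes over 2-fold in total RNA and 1.66. A minimum of 1 in both fractions gave 334 genes over 2-fold nuclear and a lncRNA median of 1.47. The cause was not tested. The other 30 of 58 values moved less, counts by under 1.5 times and medians by under 0.1 on the log2 scale. The number reversed was 0, but a count of calls cannot reverse. On the unscaled quotient 51 of the 725 RefSeq genes called in total RNA without a group at 0 took the other sign. Of the values of lists and named genes, 274 of 353 stayed and 79 moved, 62 of them list counts at log2 over 1. Not run for want of values per pool were DESeq2, RLE factors, library sizes from each table, no count filter, only the compared groups in the fit, separate fits, a lane covariate, leave-one-out, camera and fry, and the lncRNA share of counts. No paired analysis was possible because the tables hold 1 mean per group, so no replicate block could be fitted. Depth limits what low lncRNAs can show, and 255 lncRNAs reached 1 RPKM in total RNA and 1228 in nuclear RNA.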

Other observations

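The split of lncRNA calls at 1 RPKM and above it, the match on level and fold together and the genes of the first paragraph were chosen after their values were seen, and the other tests of lncRNA calls and of neighbouring genes before.

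Several genes passed the threshold in 1 fraction of the authors' deposited table and not in the other, a contrast that was itself not tested. Metallothioneins, which bind zinc and copper, were female higher in nuclear RNA, with Mt1 at 37.7 FPKM in females and 18.3 in males (log2 -0.91) and Mt2 at 32.6 FPKM in females and 16.1 in males (log2 -0.89) in the authors' deposited table, and at log2 -0.12 and 0.13 they were not called in total RNA. Lbp, which binds bacterial lipopolysaccharide, was at 16.7 FPKM in females and 8.44 in males (log2 -0.87) in nuclear RNA and, not called, at log2 -0.21 in total RNA in the authors' deposited table. In total RNA the growth factor receptor gene Egfr was male higher at 15.8 FPKM in females and 26.8 in males (log2 1.14), and at log2 0.23 in nuclear RNA it was not called in the authors' deposited table. The serum amyloid gene Saa3 was male higher in total RNA at 1.09 FPKM in females and 3.14 in males (log2 1.95) and not called in nuclear RNA at log2 0.12 in the authors' deposited table. Mt1, Mt2, Lbp and Saa3 are among the 32 other acute-phase genes already weighed, so they are no separate evidence.

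More lncRNAs were called in nuclear RNA (641) than in total RNA (145) in the authors' deposited table. With the nuclear call rate of each RPKM bin 169 calls would be expected in total RNA, 1.17 times the observed number, but this closeness rests on lncRNAs under 1 RPKM (107 expected, 112 observed), where it is consistent with fewer reads per lncRNA although 9 of these calls lay under 0.1 RPKM, where nuclear RNA had 0. At 1 RPKM or more 62.7 calls would be expected (24.6% of 255) against 33 observed (12.9%, Wilson interval 9.37 to 17.6) in the authors' deposited table. The numbers were 30.3 expected and 12 observed at 1 to 2 RPKM, and close at 2 to 10 RPKM (22 expected and 19 observed). The gap at 1 to 2 RPKM cannot decide whether fewer reads are the whole cause. False discovery rates were adjusted within each fraction, so fewer calls make the p cutoff stricter at every level. At 10 RPKM or more 10.5 calls were expected and 2 observed, at a median of 17.7 RPKM in total and 22.4 in nuclear RNA. That lower median does not settle it, as nuclear lncRNAs at 5 to 10 RPKM were called at 25.8% (18.8 to 34.3). The total RNA share at 10 RPKM or more was 7.69% (2.14 to 24.1, 26 lncRNAs), and this range stays open. Among lncRNAs at 1 RPKM or more with an absolute log2 of 0.5 to 2, 16.1% (14 of 87, 9.83 to 25.2) were called in total RNA, where 38.9 calls would be expected with level and fold matched (16.6 against 4 observed at 1 to 2 RPKM), and 44.5% (195 of 438, 39.9 to 49.2) in nuclear RNA in the authors' deposited table. RefSeq genes chosen by the same limits were called in 61.6% (351 of 570, 57.5 to 65.5) in total RNA in the authors' deposited table. In nuclear RNA the share was 59.9% (445 of 743, 56.3 to 63.4) in the authors' deposited table. These genes were not matched on level. Of all called RefSeq genes at 1 FPKM or more, 304 of 566 reached 5 FPKM in total and 288 of 779 in nuclear RNA. Whether the total RNA pools spread more widely therefore cannot be told from these shares. A spread limited to lncRNAs and transcript length, which was not matched, stay open too.

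The shared direction of neighbouring lncRNAs and genes was tested for read-through from the gene's own strand. In nuclear RNA 91.7% of all pairs and 92.2% of the 231 pairs on opposite strands had a common direction in the authors' deposited table, the latter above the permuted 95th percentile of 57.6% (permutation p = 0.0001, the smallest the permutations can give), which argues against own-strand read-through as the whole cause. Opposite-strand pairs without overlap gave 89.9% (142 of 158) in the authors' deposited table. In total RNA the opposite-strand pairs gave 71.4% (35 of 49, permutation p = 0.0070) and those without overlap 65.8% (25 of 38, permutation p = 0.0538) in the authors' deposited table, so the latter missed the threshold. That position beside a gene of the same direction may account for the pattern is a hypothesis, and pairs of 1 gene cluster and unstranded counting stay open.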
